A study of Mus musculus with 6 samples.

How the data were processed

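The series holds 6 samples of back-skin keratinocytes from 9.5 week old female mice on a mixed strain background, 3 wild type and 3 K14ΔNLef1, grouped by the genotype and replicate number in the sample titles. Per the labels' protocols, RNA was extracted after fluorescence-activated sorting with a micro-scale column kit, amplified with a whole-transcript kit for small amounts, labelled with biotin and hybridised to a mouse exon array. The labels call the samples biological replicates and name no pairs.

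The deposited table gives 1 linear intensity per probe set and array. Per the submitters' processing notes, RMA, Affymetrix Power Tools and the mm9 build were used, with versions not given in the sources used here. The log2 of 100% of the deposited intensities is a number of 5 decimals to within 2e-08, so the values look like log2 values raised to a power of 2, and log2 was taken before every test. The array medians differ, so the deposited intensity values do not share 1 distribution over these probe sets. Any filter on probe sets is not given in the sources used here.

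Probe sets were named through the platform annotation of gene symbols. Of 114330 probe sets, 109751 had 1 symbol, 834 had several and 3745 had none listed, and only those with 1 symbol were used for genes. Older symbols were updated through synonyms of the GRCm38.p6 gene table for 1226 symbols, after which 11244 of 11281 were found in it. That table lists 21896 protein-coding genes, of which 11215 were measured here, so other genes were not analysed here. It was used only for names and for the order of neighbouring genes. The positions of probe sets were not used here.

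A gene's value on an array is the mean log2 intensity of its probe sets, from 1 to 99 of them, and 725 genes had 1. Genes were tested with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, two-sided) with Benjamini-Hochberg adjustment and a threshold of 0.05, with no filter on low values. The same fit was run per probe set, and diffSplice tested whether the probe sets of a gene changed unequally, in genes with at least 3. Gene lists were tested with camera at a preset correlation of 0.01 in the 28 of 29 lists with at least 5 measured members, Benjamini-Hochberg over lists, and again with an estimated correlation and with fry, whose p asks whether a list's genes move one way on balance. The lists hold 690 genes, of which 535 were measured, and they were fixed from general knowledge of mouse epidermis. The design, the lists, the rule for named genes and all alternatives but 1 were fixed before the data were examined.

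The named genes are Lef1, the 15 with the largest rise and the 15 with the largest fall among genes that passed and whose genotypes did not overlap, and in each list up to 4 members that passed with the largest change or, where none passed, the 2 with the smallest p. Not every list member chosen by the rule is described. Genes of families with near-identical copies are given as uncertain.

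The tests were tested on simulated data with the real probe set means and spreads, for 3 K14ΔNLef1 arrays against 3 wild type arrays. Among 11281 simulated genes, 30.8% of those changed by a log2 of 1 passed, 95.5% of those changed by 2 and 100% of those changed by 3, and 12 unchanged genes passed. Among 9818 genes tested for unequal change, 94% of those with a log2 change of 2 in a part of their probe sets passed, and 13 others did. Of 109751 probe sets, 94.5% of those changed by 3 passed and 64 unchanged ones did. All probe sets of each changed gene were changed there, many more than the 199 that passed in the real data, which eases the adjusted threshold. The real test per probe set was less sensitive: a Lef1 probe set that rose by 7.00 had a limma adjusted p of 0.0365. The 2 shifted lists passed with camera, with an estimated correlation and with fry, and 0 of the other lists did. Genes were simulated independently of each other, so the effect of correlation within lists was not tested this way. The simulated spread was the same on all arrays, so an array noisier than the others, as K14ΔNLef1 replicate 1 was, was not tested either.

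The alternatives were the median of a gene's probe sets, the brighter probe sets only, filters on dim genes or probe sets, genes with at least 4 probe sets, arrays shifted to the same median, quantile normalization, eBayes with trend and robust settings, a test without moderation, array weights, an adjusted p of 0.1, a change of at least 1.5-fold, blocks by replicate number or by adjacent sample numbers in the descriptions, the array number as a covariate, each replicate left out, and camera with an estimated correlation, fry and camera on ranks. K14ΔNLef1 replicate 1 left out with the other arrays quantile normalized was chosen after seeing the data. Data were read and drawn with Python 3.11.15, pandas 2.3.3 and matplotlib 3.10.9.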

Results

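Gene expression was measured in keratinocytes from the back-skin epidermis of 9.5 week old female mice, taken without sorting into subsets of keratinocytes. Samples from 3 wild type mice were compared with samples from 3 K14ΔNLef1 transgenic mice, which carry a form of the Wnt pathway transcription factor Lef1 that lacks its N-terminal part, under the keratin 14 promoter of basal epidermal cells. The comparison asks how this transgene changes expression in the epidermis. The 6 samples are named biological replicates in the labels, and each was hybridised to 1 exon array, on which a gene is read by several probe sets. The table holds 114330 probe sets, of which 109751 belong to 1 of 11281 genes, with a median of 8 probe sets per gene. Median intensity was 196.4, 190.2 and 199.8 on the wild type arrays and 154.2, 190.0 and 203.2 on K14ΔNLef1 replicates 1, 2 and 3. The number of arrays limits the precision. Gene values below are means of the log2 intensities of a gene's probe sets, given as mean ± SD with n = 3 arrays per genotype, and changes are K14ΔNLef1 minus wild type on the log2 scale.

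Lef1 was far higher in every transgenic sample. Its gene value was 6.36 ± 0.61 in wild type and 11.16 ± 0.07 in K14ΔNLef1 (SD, n = 3), with values of 5.81, 7.02 and 6.26 against 11.11, 11.13 and 11.24. The rise of 4.80 (SE 0.29), or 27.8-fold, passed the test with a limma adjusted p of 4.02e-04, and it was the largest rise among the genes that passed. The rise was not shared by all parts of the gene. Of the 13 Lef1 probe sets, 10 rose, by 4.65 to 7.54, with adjusted p between 0.00181 and 0.0365. Those calls depended on single arrays: 2, 7 and 0 of the 10 passed without wild type replicate 1, 2 and 3, and 8, 4 and 3 without K14ΔNLef1 replicate 1, 2 and 3, though their differences stayed at 4.47 or more. The other 3, probe sets 4593025, 5304528 and 4936262, differed by 0.39, -0.17 and -0.36, with adjusted p of 0.854, 0.919 and 0.797. Where these 3 lie in the gene was not analysed here.

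**Figure D1:**
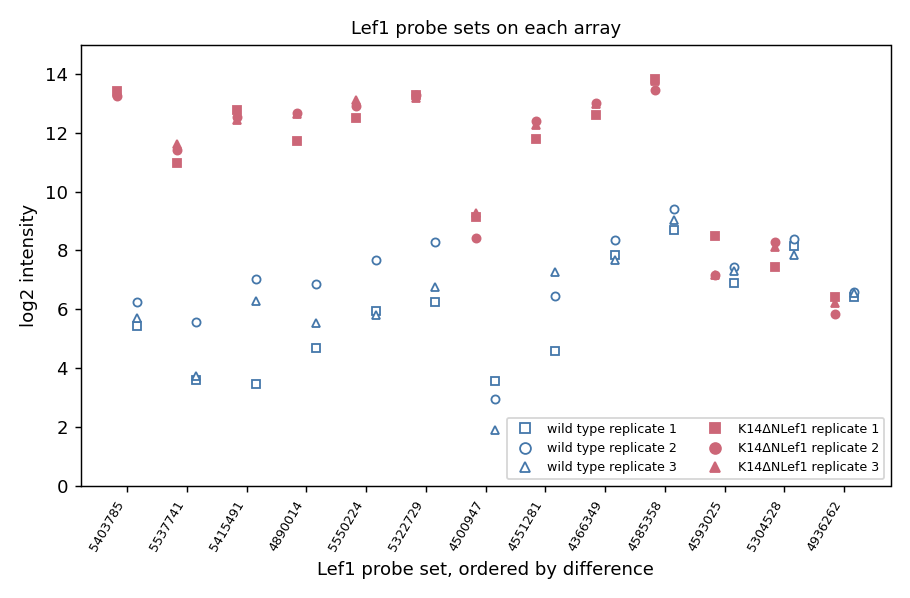
Log2 intensity of the 13 Lef1 probe sets (horizontal axis, ordered by difference) on each of the 6 arrays, with open symbols for wild type and filled symbols for K14ΔNLef1 and a symbol shape per replicate. In 10 probe sets all filled symbols lie above all open symbols, with rises of 4.65 to 7.54, and the last 3 differ by 0.39, -0.17 and -0.36.

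Across the genes, more fell than rose. Among those that rose most were Fmo1, a flavin-containing monooxygenase, by 3.65 (SE 0.24), Pla2g4c, a cytosolic phospholipase, by 3.16 (SE 0.20), and Igfbp2, a binding protein of insulin-like growth factors, by 2.71 (SE 0.20). Among those that fell most were Serpinb2, an inhibitor of plasminogen activators, which fell by 3.83 (SE 0.22), the decoy interleukin receptor Il1r2, which fell by 3.75 (SE 0.25), and the alarmin cytokine Il33, which fell by 3.43 (SE 0.21). In total 37 genes rose and 94 fell of 11281 (limma, adjusted p at or under 0.05). All 131 had no overlap between the genotypes, which a call at this threshold makes likely with 3 arrays each, so it is no separate support. Of all genes 18.7% had no overlap, where chance gives 10%. Of the 131, 127 changed at least 2-fold.

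Among the other genes with the largest rise, Tagln3, of the actin-associated transgelin family, went from 5.78 ± 0.34 to 9.11 ± 0.30, and Cald1, the actin-binding caldesmon, from 6.61 ± 0.22 to 9.15 ± 0.60 (SD, n = 3). The protease inhibitors Serpinb11 and Serpine2 rose by 3.31 and 2.64, with adjusted p of 0.0138 and 0.0142. The lipoprotein receptor gene Vldlr rose by 2.42, Myef2 by 2.68, Pcbd1, a pterin dehydratase, by 2.59, and the G protein subunit gene Gng11, read by 1 probe set, by 2.14. Spo11, which makes meiotic DNA breaks, rose by 2.24 and the axonemal dynein gene Dnah8 by 2.20. The progesterone receptor gene Pgr rose by 2.15 (adjusted p of 0.0339).

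Among the other genes with the largest fall, Il20ra, a subunit of receptors of the interleukin 20 family, fell by 3.56, the guidance factor gene Sema3d fell by 3.53, the lymphatic growth factor gene Vegfd fell by 2.94 and Rspo3, which enhances Wnt signalling, fell by 2.64. Ackr2, a receptor that scavenges chemokines, went from 9.05 ± 0.28 to 6.55 ± 0.54 (SD, n = 3). The chromatin organiser gene Satb1 fell by 3.02, the chitinase gene Chit1 fell by 2.57, Fam81a fell by 2.54 and the serpin gene Serpinb7 fell by 2.85. Skint10 fell by 3.25 and Skint7 fell by 2.73. Skint and Serpinb genes belong to families with closely similar copies, and Skint7 was read by 1 probe set, so the values of these genes are uncertain. The skin calmodulin-like gene Calm5 fell by 2.70 (adjusted p of 0.0379).

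**Figure D2:**
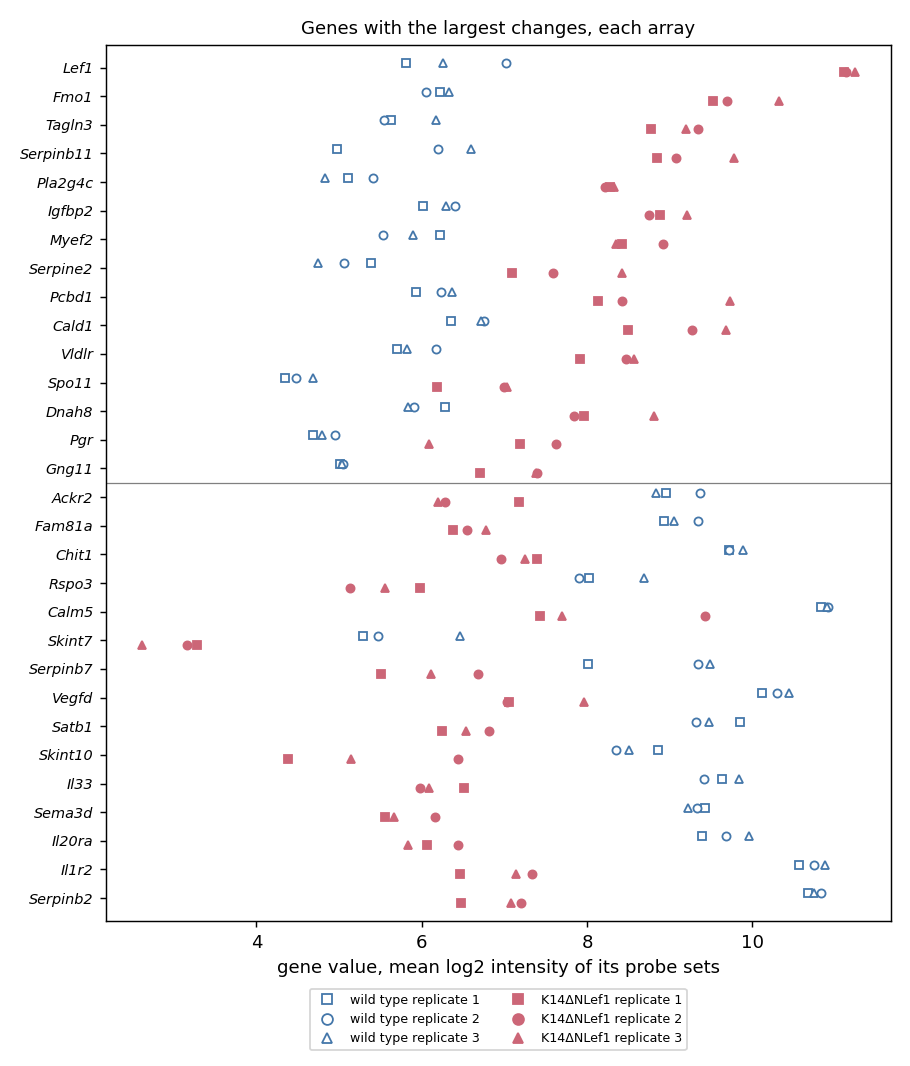
Gene value (mean log2 intensity of the gene's probe sets, horizontal axis) of the genes with the largest rise (above the line) and the largest fall (below it) on each array, open symbols for wild type and filled for K14ΔNLef1. By the rule for named genes, the 3 arrays of a genotype lie on 1 side of the other 3 in every gene. The genes run from Lef1 with a rise of 4.80 to Serpinb2 with a change of -3.83.

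The split between rises and falls depended on 1 array and on scaling. Without K14ΔNLef1 replicate 1, 115 genes rose and 124 fell, and 123 of the 131 genes passed again. With the arrays shifted to the same median 101 rose and 133 fell, and with quantile normalization 89 rose and 112 fell. The median change of all genes was -0.054 as deposited, 0.054 with the same medians and 0.056 after quantile normalization. Leaving out a wild type replicate 1, 2 or 3 left 46, 31 or 28 genes, and leaving out K14ΔNLef1 replicate 2 or 3 left 77 or 69. Of the 36 other named genes that passed beside Lef1, 10, 18 and 14 missed the threshold without wild type replicate 1, 2 and 3, and 2, 6 and 7 without K14ΔNLef1 replicate 1, 2 and 3. The 2 were Pgr and Calm5, with adjusted p of 0.0649 and 0.0609 without replicate 1, and with 1 array left out these genes ranged from 0.00468 to 0.156 and from 0.00191 to 0.166. Each passed in 1 of those 6 fits. Of the other genes with the largest changes, Pcbd1 and Skint10 passed in 2 of the 6 limma fits with 1 array left out and Serpinb7 in 3. Their adjusted p reached 0.107, 0.0978 and 0.120.

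In the Wnt and hair follicle lists, few members passed. Of 19 measured Wnt targets and feedback genes, 1 fell and 18 did not pass. The gene that fell was Sostdc1, a secreted inhibitor of BMP and Wnt signals, at 10.15 ± 0.21 in wild type and 8.32 ± 0.45 in K14ΔNLef1 (SD, n = 3). Its adjusted p was 0.0170, and 0.0159 to 0.0978 with 1 array left out, where it passed in 2 of 6 fits. Adjusted over the list alone, 1 of these genes rose and 3 fell. Sostdc1 was also the 1 of 12 upper follicle markers that passed. None of 24 bulge stem cell markers passed, and the 2 with the smallest p were Wif1, with a change of 1.16 (adjusted p of 0.125), and Cd34, with 0.61 (adjusted p of 0.189). Of 25 hair shaft and inner root sheath genes, 1 passed, Gata3, a transcription factor of the inner root sheath and epidermis, which fell by 1.35 (adjusted p of 0.0181, and 0.0108 to 0.101 with 1 array left out). Gata3 passed in 3 of those 6 fits. None of 12 Hedgehog, 18 Notch or 21 BMP and TGF-beta genes passed. Adjusted over the list alone, 1 upper follicle gene fell, 1 hair gene rose and 2 fell, and no bulge, Hedgehog, Notch or BMP gene passed. The mean changes of these 7 lists were -0.128 for Wnt, -0.244 for upper follicle, 0.007 for bulge, -0.046 for hair, 0.097 for Hedgehog, 0.008 for Notch and -0.107 for BMP and TGF-beta, with none past the camera threshold. The means without K14ΔNLef1 replicate 1 were -0.141, -0.042, 0.115, -0.028, 0.117, 0.017 and 0.009 in the same order, and the upper follicle mean was -0.648 on that array alone. Also without it, 1 upper follicle gene, Atp6v1c2, and 1 hair gene, Krt27, rose, both named after their values were seen, and Sostdc1 and Gata3 fell as before.

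Among the epidermal layers, 2 suprabasal keratins moved in opposite directions. Krt77 fell from 11.73 ± 0.06 to 9.76 ± 0.42 and Krt2 rose from 5.95 ± 0.14 to 7.73 ± 0.54 (SD, n = 3), while 28 of 30 suprabasal and cornified layer genes did not pass. With 1 array left out the adjusted p of Krt77 was 0.00261 to 0.0664 and that of Krt2 was 0.00225 to 0.127. Krt77 passed in 4 of these 6 fits and Krt2 in 1, the fit without K14ΔNLef1 replicate 1. Adjusted over the list alone, 3 of the 30 rose and 4 fell. None of 22 basal keratinocyte genes passed with all arrays. The nearest were the integrin gene Itga2, with a change of -1.26 (adjusted p of 0.0680), and the P-cadherin gene Cdh3, with 0.82 (adjusted p of 0.170), and without K14ΔNLef1 replicate 1 both passed (adjusted p of 0.0295 and 0.0233). Adjusted over the list alone, 1 basal gene and 1 stress gene fell. Of 24 stress keratins, alarmins and small proline-rich proteins, 1 passed, Ptgs2, an enzyme of prostaglandin synthesis, which fell by 1.97 (adjusted p of 0.0204, and 0.0203 to 0.0998 with 1 array left out). Ptgs2 passed in 2 of those 6 fits. The list means were -0.124 for suprabasal, -0.181 for basal and 0.152 for stress genes, and none passed the camera threshold. The stress list did pass without K14ΔNLef1 replicate 2, with a mean of 0.308 (camera adjusted p of 0.0123, and 0.624 there with an estimated correlation). K14ΔNLef1 replicate 1 carried the first 2 means, at -0.410 and -0.469, and without it the means were 0.019, -0.036 and 0.128, with Krt2 rising and Krt77 and, named after its values were seen, Abca12 falling.

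In the lipid and metabolic lists, sebocyte genes were higher as a list. Its camera adjusted p was 0.0308, and adjusted p = 0.681 with an estimated correlation. The list had a mean of 0.187 and a median of -0.002, with 12 of 25 members higher. The mean was -0.127 on K14ΔNLef1 replicate 1, 0.241 on replicate 2 and 0.446 on replicate 3, and it was 0.344 without replicate 1 and 0.057 without replicate 3. The list did not pass without wild type replicate 2, K14ΔNLef1 replicate 2 or K14ΔNLef1 replicate 3 (adjusted p of 0.0856, 0.0784 and 0.159). No member of the 25 passed over all genes, and 6 rose when adjusted over the list alone. Without K14ΔNLef1 replicate 1, 3 sebocyte genes passed over all genes, Mgst1, Soat1 and Ldhb (adjusted p of 0.0207, 0.0377 and 0.0372), and 3 glutathione genes, Mgst1, Akr1b8 (0.0241) and Gsta3 (0.0347), all higher. Ldhb and Gsta3 were named after their values were seen. The members with the smallest p were Mgst1, a microsomal glutathione transferase, with 1.76 (adjusted p of 0.0517), and Soat1, which esterifies cholesterol, with 1.46 (adjusted p of 0.144). Mgst1 also led the 23 glutathione and xenobiotic genes, with Akr1b8 at 1.73 (adjusted p of 0.0578). None of those 23 passed over all genes, and 4 rose and 1 fell adjusted over the list alone. None of 13 cholesterol synthesis enzymes passed, over all genes or adjusted over the list alone. Of 19 retinoid genes, Aldh1a2, an enzyme of retinoic acid synthesis, rose by 1.45 (adjusted p of 0.0212, and 0.00537 to 0.122 with 1 array left out), the 1 retinoid gene that passed adjusted over the list alone. With 1 array left out Aldh1a2 passed in 1 of 6 fits, the fit without K14ΔNLef1 replicate 1. The list means were 0.275 for glutathione, -0.076 for cholesterol and 0.109 for retinoid genes, none past the threshold. The cholesterol mean was -0.349 on K14ΔNLef1 replicate 1, and without that array the 3 means were 0.398, 0.060 and 0.162.

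Lists of growth and stress genes moved in different directions. The p53 target list was lower (camera adjusted p of 0.00187, mean -0.375), with 21 of 24 members lower, and adjusted p = 0.586 with an estimated correlation. The p53 list averaged -0.622, -0.305 and -0.199 on K14ΔNLef1 replicates 1, 2 and 3, and its mean was -0.252 without replicate 1. Its 1 member that passed was Cdkn1a, a cell cycle inhibitor, which fell by 1.26 (adjusted p of 0.0339, and 0.0294 to 0.173 with 1 array left out), and it was the 1 that passed adjusted over the list alone. Cdkn1a passed in 2 of the 6 fits with 1 array left out. The immediate early and heat shock list was lower too (adjusted p of 0.00313, mean -0.403, 21 of 24 members lower), with adjusted p = 0.667 with an estimated correlation. None of its members passed, also adjusted over the list alone, and the nearest were Klf4 with -0.91 and Zfp36 with -0.87. The list averaged -0.710, -0.340 and -0.159 on K14ΔNLef1 replicates 1, 2 and 3, with wild type replicate 3 at -0.178, below K14ΔNLef1 replicate 3. Its mean was -0.249 without K14ΔNLef1 replicate 1. The cell cycle list was higher (adjusted p of 0.00824, mean 0.153, 24 of 35 members higher), with adjusted p = 0.695 with an estimated correlation. No cell cycle gene passed, and those with the smallest p went apart, Birc5 with 0.70 and Cdc6 with -0.66. Cell cycle genes averaged -0.244 on K14ΔNLef1 replicate 1, 0.253 on replicate 2 and 0.450 on replicate 3, and the list did not pass without replicate 2 (adjusted p of 0.0742) or replicate 3 (0.159). Its mean was 0.352 without replicate 1, where Ccna2 and Kif11, named after their values were seen, rose, and 0.005 without replicate 3. Interferon response genes were higher as a list (adjusted p of 0.0266, mean 0.163), though lower on 1 of the 3 transgenic arrays, with adjusted p = 0.586 with an estimated correlation, and none of 17 passed, with Zbp1 at 0.42 and Rsad2 at 0.52. Interferon genes averaged -0.110, 0.357 and 0.241 on K14ΔNLef1 replicates 1, 2 and 3, with wild type replicate 1 at 0.141. Their mean was 0.299 without K14ΔNLef1 replicate 1, where Cxcl9, also named after its values were seen, rose, 0.066 without K14ΔNLef1 replicate 2 and 0.092 without wild type replicate 2. That list did not pass without wild type replicate 2 (adjusted p of 0.123) or K14ΔNLef1 replicate 2 (0.16), and its mean was -0.130 with dim genes left out.

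T cell and Langerhans cell markers were higher on K14ΔNLef1 replicates 2 and 3 than on replicate 1. T cell markers averaged 1.26 above the wild type mean on K14ΔNLef1 replicate 2 and 0.74 on replicate 3, against -0.25 on replicate 1, and Langerhans cell and antigen presentation markers averaged 1.16, 0.54 and 0.06 in the same order. The wild type arrays spread too, with T cell means of 0.343, -0.295 and -0.048 on replicates 1, 2 and 3. Their Langerhans means were 0.366, -0.292 and -0.074. Other immune lists did not share the pattern. On K14ΔNLef1 replicates 1, 2 and 3, macrophage, monocyte and neutrophil markers averaged 0.130, 0.211 and 0.069, and mast cell markers -0.111, 0.036 and -0.113. Both lists passed the camera test (adjusted p of 1.27e-05 each), with 21 of 22 and 18 of 19 members higher, and adjusted p = 0.624 for T cells and 0.586 for Langerhans cells with an estimated correlation. The T cell mean of 0.584 was 0.999 without K14ΔNLef1 replicate 1 and 0.245 without replicate 2, and the Langerhans mean of 0.587 was 0.301 without replicate 2. No member passed, over all genes or adjusted over the list alone. The nearest were Gzmc, a granzyme, with 1.72 (adjusted p of 0.231), Cd2 with 0.84, Mfge8 with 0.86 and Fcer1g with 0.74. Without replicate 1, Gzmc had an adjusted p of 0.0241 and Cd2 of 0.0447.

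Of the lists of other cell types, 4 were higher. Fibroblast markers (adjusted p of 8.64e-04, mean 0.307, 18 of 20 higher), melanocyte markers (adjusted p of 0.00187, mean 0.262, 9 of 12 higher), endothelial, pericyte and smooth muscle markers (adjusted p of 0.00664, mean 0.174) and macrophage, monocyte and neutrophil markers (adjusted p of 0.0366, mean 0.137) passed the camera test. With an estimated correlation these had adjusted p = 0.586 for fibroblasts, melanocytes and macrophages and 0.667 for endothelial cells. The estimate was only 0.031 for fibroblasts and 0.051 for macrophages, against 0.123 for melanocytes and 0.375 for endothelial cells. How much of the higher p comes from correlation was not tested. No member of these lists passed over all genes, and adjusted over the list alone 3 fibroblast markers rose and 1 fell. The genes with the smallest p were Sparc with 0.92 and Fbln1 with 1.02 for fibroblasts, Tyr with 0.60 and Gpnmb with 0.82 for melanocytes, Acta2 with 1.04 and Lyve1 with 0.61 for vessels, and Cd14 with -0.54 and Camp with 0.35 for macrophages. Without K14ΔNLef1 replicate 1 the endothelial and macrophage lists no longer passed (adjusted p of 0.493 and 0.453). The endothelial mean was 0.084 without that array and 0.273 without K14ΔNLef1 replicate 2, on which it was -0.024. The macrophage list also missed the threshold without wild type replicate 2 (0.0823), wild type replicate 3 (0.117) or K14ΔNLef1 replicate 2 (0.0934). Mast cell, Merkel cell, skeletal muscle and adipocyte lists did not pass, with means of -0.063, -0.004, 0.026 and 0.128, and only 2 erythrocyte markers were measured, with a mean of -0.054. These 5 means were -0.038, -0.092, -0.042, 0.126 and -0.107 without K14ΔNLef1 replicate 1. Of the 28 lists tested, 11 passed, 9 higher and 2 lower, and 0 passed in camera with an estimated correlation, where 1 had an unadjusted p under 0.05, or with fry, where 4 did. The camera test compares a list with all other genes, and its direction was up for the suprabasal, hair, BMP, mast cell and Merkel cell lists although their means were negative. Mean and median differed in sign for the Wnt, bulge, sebocyte, hair, BMP, mast cell, Merkel cell and muscle lists. The fibroblast, melanocyte, endothelial and macrophage lists were dim, with mean log2 levels of 6.87, 6.75, 6.29 and 6.36. The lower p53 and immediate early lists were brighter, at 7.99 and 8.54. Mast cell and Merkel cell lists were also dim, at 6.55 and 6.65, without a higher mean. The median change of all genes was -0.054, and -0.141 with dim genes left out. Whether list direction depends on signal level was not tested.

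**Figure D3:**
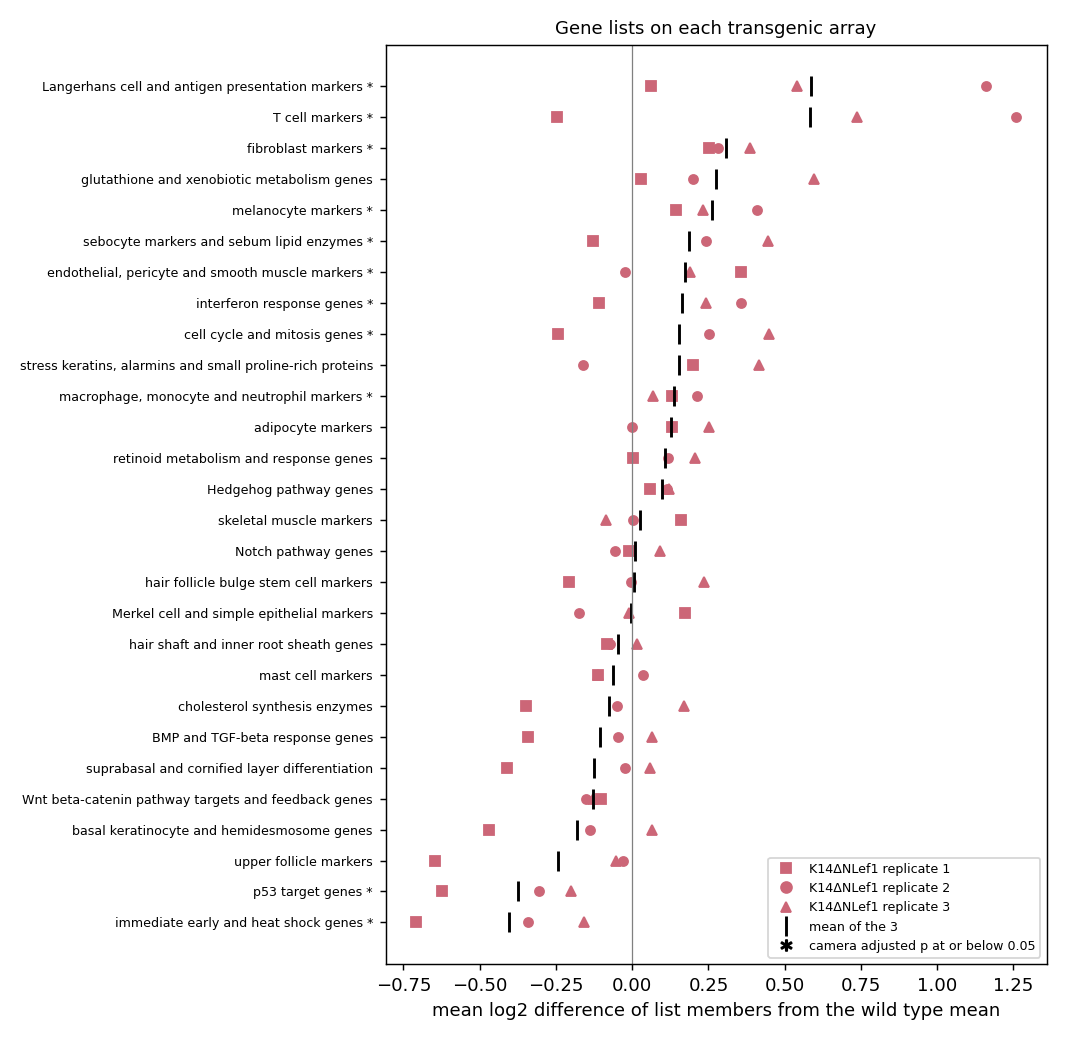
Mean log2 difference of each list's members from the wild type mean (horizontal axis) on each K14ΔNLef1 array, with a bar at the mean of the 3 arrays and a star at lists with a camera adjusted p at or below 0.05. The T cell list lies at 1.26 and 0.74 on replicates 2 and 3 and at -0.25 on replicate 1.

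Single probe sets and unequal change within genes were tested because the array reads parts of genes. Of 114330 probe sets 73 rose and 126 fell, and those with 1 gene symbol came from 76 genes, of which 58 were among the changed genes. Of 9818 genes with at least 3 probe sets, 74 had probe sets that changed unequally, 45 of them also changed genes. The smallest p belonged to Lama1, a laminin chain, with 65 probe sets (adjusted p of 2.58e-18, limma diffSplice), followed by Wnt5a (8.21e-16), a Wnt ligand whose gene value fell by 2.32, Lef1 (8.83e-16), the nuclear pore gene Nup210 (7.74e-15) and Adgrv1 (6.78e-14). These 5 were chosen after their values were seen, except Lef1. The test pools the spread of a gene's probe sets on the same 6 arrays, so a gene with many probe sets can reach a smaller p. Nup210 and Adgrv1 had 43 and 58 probe sets, and Wnt5a and Lef1 had 12 and 13. The gene value of Lama1 differed by -0.83 and that of Adgrv1 by -0.18, neither past the threshold, and that of Nup210 rose by 1.44. Without K14ΔNLef1 replicate 1, 140 genes changed unequally, and without wild type replicate 1, 2 or 3 the number was 35, 30 or 37. Without wild type replicate 1, 2 or 3 the number of changed probe sets was 6, 11 or 0, with 6805 at an unadjusted limma p under 0.05 in the last case, and without K14ΔNLef1 replicate 2 or 3 it was 45 or 16.

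The arrays of each genotype lay together except for 1. Across genes, which are not independent replicates, Pearson's r was 0.967 to 0.971 among the wild type arrays, 0.967 between K14ΔNLef1 replicates 2 and 3, and 0.938 to 0.949 between the wild type arrays and these 2. K14ΔNLef1 replicate 1 had an r of 0.881 to 0.908 with the other 5 arrays. The first principal component, with 48.6% of the variance, set this array apart, and the second, with 24.7%, separated K14ΔNLef1 replicates 2 and 3 from the wild type arrays, with K14ΔNLef1 replicate 1 on the wild type side. The probe sets of a gene, each set against its own mean on the other arrays, also scattered more on it, with a median SD within a gene of 0.753 log2 units against 0.465 to 0.486 on the others, over 5738 genes with at least 8 probe sets.

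**Figure D4:**
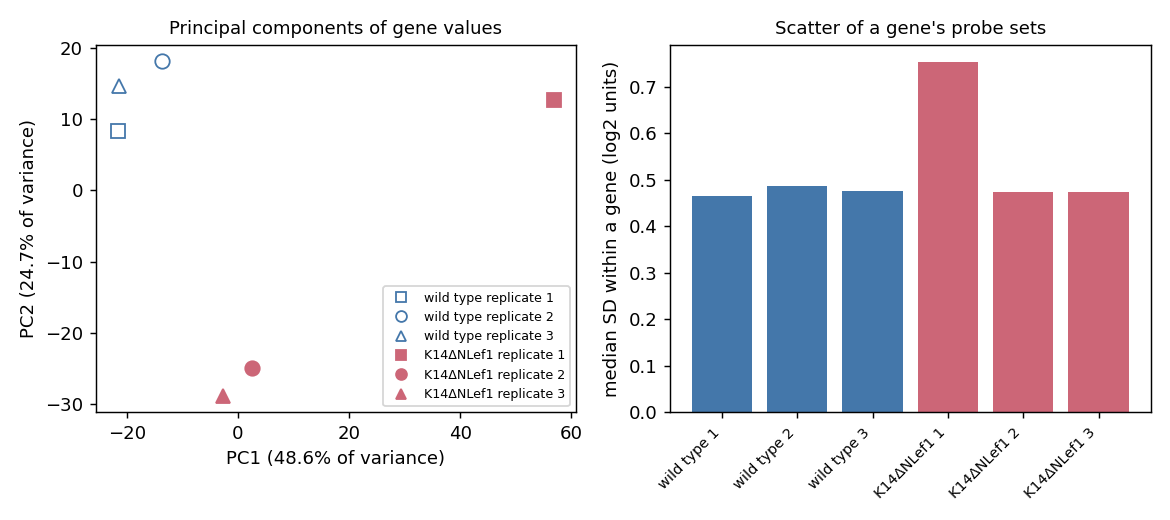
Left, the first (horizontal) and second (vertical) principal components of gene values, with 48.6% and 24.7% of the variance, for the 6 arrays (open symbols wild type, filled K14ΔNLef1). Right, bars from 0 of the median SD, within a gene, of its probe sets' differences from their own means on the other arrays, in log2 units, which is 0.753 for K14ΔNLef1 replicate 1 and at most 0.486 for the others.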

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

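The tests of noise and of Lef1 level on K14ΔNLef1 replicate 1 and the test of T cell markers against melanocyte markers were chosen after the values were seen. Among the 4579 probe sets with several gene symbols or none, which no gene value uses, 2 passed, both higher in K14ΔNLef1 than in the control samples. Probe set 4941213 was 5.70 in wild type and 8.73 in K14ΔNLef1, a rise of 3.03 (SE 0.40, limma adjusted p of 0.0493), and probe set 5510621 was 8.90 and 11.93, a rise of 3.04 (SE 0.36, adjusted p of 0.0365). Each was higher in 3 of 3 transgenic samples than in all wild type samples, and their genes were not analysed here.

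K14ΔNLef1 replicate 1 stood apart from the other 5 arrays. A higher transgene level in that animal was not seen, but it stays open. Its Lef1 value was -0.079 log2 units from the mean of replicates 2 and 3, where the SD of the 3 was 0.071. A difference of 0.5 was needed. The values were not rescaled, and this array was the dimmest, with a median intensity of 154.2 against 190.0 and 203.2. Its median log2 was 7.269 against 7.570 and 7.666, a gap too small to bring the Lef1 difference to 0.5. Some Lef1 probe sets lay near the highest intensity measured, such as 13.42 and 13.83 on replicate 1, where a further rise could hardly show. Of the dimmer ones that rose, 5537741, 4890014 and 4551281 were lower on replicate 1 than on replicates 2 and 3. Probe set 4500947, at 9.14, lay between 8.42 and 9.27. All this rests on 1 noisy array, so the test cannot decide. Noisier probe sets on that array are consistent with the data: the median scatter of a gene's probe sets was 0.753 there and at most 0.486 on the others. What made the array noisy, such as the amount or state of its RNA, was not tested, and a difference between the animals stays open.

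T cell and Langerhans cell markers were higher on K14ΔNLef1 replicates 2 and 3 than on replicate 1, and a lower share of keratinocytes could raise the markers of all other cell types alike. The 23 immune markers brighter than the median gene rose by 0.787 (SE over markers 0.353) more than melanocyte markers, but only 3 melanocyte markers were that bright, so this stays open. That SE treats markers on the same arrays as independent and holds no spread between animals. Lost sensitivity on the replicate 1 array also stays open: 113 genes outside the immune lists that rose without that array had a median change on it of 0.478 (SE 0.047, likewise over genes) of that on the other 2, just under the 0.5 set to decide and within its error of it. The requirement to clear 0.5 by that error was added after the value was seen, and these genes were picked as higher on those 2 arrays, which lowers the share. A difference in immune cells between genotypes or animals stays untested.

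The real split of the 6 arrays gave 131 genes, 199 probe sets, 74 genes with unequal change and 11 lists, in 1 of 10 splits each as large. The highest of the other splits gave 0 genes, 0 probe sets, 25 genes with unequal change and 8 lists. With 10 splits the share is too coarse to fall under 0.05.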

How the results depend on the processing

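1 alternative, K14ΔNLef1 replicate 1 left out with the other 5 arrays quantile normalized, was chosen after seeing the data. The cause was not tested for any shift below unless it is named. Lef1 rose under all settings run, and passed in all but the test without moderation (a log2 rise of 4.80, adjusted p of 0.0841). From 131, the count of changed genes was 234 with the arrays shifted to the same median, 201 with quantile normalization, 1297 with array weights, 236 at an adjusted p of 0.1, 75 with the replicate block, 78 with the array number as a covariate, 238 with the added alternative, and 0 without moderation, where 1108 had an unadjusted p under 0.05. It was 28 to 239 with a replicate left out, and fewer arrays lower the degrees of freedom. From 199, the count of changed probe sets was 374 with the same medians, 360 with quantile normalization, 310 with trend and robust settings, 470 at 0.1, 1 without moderation, 0 with the replicate block (8522 unadjusted), 0 with the block of adjacent numbers (9126 unadjusted), and 0 to 189 with a replicate left out. From 74, the genes with unequal change were 47 with the replicate block and 30 to 140 with a replicate left out. From 11, the lists that passed were 0 with an estimated correlation and 0 with fry, with 1 and 4 at an unadjusted p under 0.05. The lowest r between arrays moved from 0.881 to 0.607 with the brighter probe sets only, and was 0.881 to 0.938 with a replicate left out. The deviations of samples of the same replicate number correlated at -0.163, -0.173 and 0.036. Those of adjacent sample numbers correlated at 0.199, -0.075 and -0.007. With 3 pairs of each kind, and K14ΔNLef1 replicate 1 apart from the others, these values cannot tell whether samples pair. Wild type replicate 1 and K14ΔNLef1 replicate 2, adjacent in number, had the highest T cell marker means of their genotypes, 0.343 and 1.26. The other adjacent samples did not rank alike. Whether a call lost under a block is a weaker effect stays open. No named gene that passed changed sign, and the mean of the interferon list, at 0.163, was -0.130 with dim genes left out. Over all pairs of a gene and a setting, named genes that passed did so again in 561 and missed the limma threshold in 106, of which 36 were without moderation. Lists that passed did so again in 151 pairs and missed it in 46. Signal over background was not given per probe set, which limits what dim genes show.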

Other observations

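The tests of chromosome 1, of gene families and of variants under single probes were chosen after the results were seen. The 6 immune receptor and ligand genes named next, outside the lists, were picked from the changed genes after their values were seen, and genes of this kind were not counted or tested as a group. Il22ra2, a soluble decoy receptor, fell by 2.35 (adjusted p of 0.0282), Il12rb2 fell by 2.18, the macrophage growth factor gene Il34 fell by 1.59 and the scavenging chemokine receptor gene Ackr3 fell by 1.06. The T cell costimulator gene Icos rose by 1.27 (adjusted p of 0.0286) and the receptor subunit gene Il18rap rose by 0.91.

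In 7 gene families, also chosen after the values were seen, 1 to 4 measured members passed, and no family was tested as a group. Of 15 measured Serpinb genes 2 rose and 2 fell, and of 6 Igfbp genes Igfbp2 rose and Igfbp3 fell by 1.41. Of 3 Fmo genes Fmo1 and Fmo2 rose, of 6 class 3 semaphorins Sema3d and Sema3c fell, of 18 Wnt genes Wnt5a fell, and of 6 Skint genes 2 fell. Skint3, Skint4 and Skint9 did not pass, and their wild type values lay far apart. They were 3.83, 3.97 and 3.39 on wild type replicate 1 and 7.26 or more on wild type replicates 2 and 3. Skint10 and Skint7, which fell, had no such drop on that array, at 8.86 and 5.29. The cause of this low signal on 1 wild type array was not tested. Of 8 receptor genes of the interleukin 1 family, Il18rap rose and Il1r2 fell. With the arrays shifted to the same median or quantile normalized, the counts were the same, except that 3 Serpinb and 3 Skint genes fell under either, and 3 of these receptor genes fell with the same median and 2 after quantile normalization.

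Changed genes lay next to each other on the chromosomes more often than chance gives. Among 11244 measured genes in genome order, 6 pairs of neighbouring changed genes were seen, where the median of 10000 shuffles was 1, and the share of shuffles with as many was 0.0036. Chromosome 1, looked at after this test, held 21 changed genes of 676 measured, 9 higher and 12 lower, against 109 of 10568 elsewhere (Fisher's exact test, two-sided, adjusted p of 6.2e-04 over chromosomes).

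Gene families lying side by side are consistent with the excess of pairs: 4 pairs join genes whose symbols share a stem, and among pairs of different stems a share of 0.400 of the shuffles had at least the 2 seen. For the count on chromosome 1, families are argued against as the whole cause, since the adjusted p was 0.0338 with each run of neighbours counted as 1, and 0.0170 with each stem counted as 1 per chromosome. A chromosome segment of 1 parental strain linked to the transgene stays open, as the pairs cannot decide it. Most pairs on 1 chromosome had been set to count for it, and pairs on several chromosomes against it. Here 4 of the 6 pairs lay on chromosome 1, and the pairs lay on 3 chromosomes. Of those on chromosome 1, only Pla2g4a with Ptgs2 joins different stems, and the rest are Serpinb and Fmo pairs. Where the changed genes lie along chromosome 1 was not analysed here. Strain variants under single probes stay open: 6 of the 21 changed genes there had unequal change, and 38 of 101 elsewhere (Fisher's exact p of 0.618). The genotype of the animals along the chromosome was not analysed here.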
